A study of Arabidopsis thaliana with 4 samples.

How the data were processed

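Small RNA libraries were made from flowers of plants grown on soil under continuous light, with total RNA isolated with Trizol and libraries prepared by a company and barcoded for 4 samples per lane, per the labels' protocols. The authors processed the reads with CASAVA 1.8.2 and name TAIR 9 as the genome build, per the submitters' processing notes. Each deposited file lists distinct sequences with their read counts. The values are raw counts, as the deposited numbers are whole and sum to a different total in each library, and no header, normalisation or genome position is given. The deposited sequences are at least 19 nt long, and no label says which step set that limit or how adapters were removed.

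Each library was its own group, taken from the labels: WT, Epi15_F8, Epi15_F11 and Epi15_F14. Reads with an undetermined base were between 0.323% and 0.335% of each library and were left out, as were reads over 30 nt, which were at most 1.00%. Sequences of 19 to 30 nt were matched to both strands of the TAIR10.1 assembly, organelles included, without mismatch, with code written for this purpose in Python 3.11.15 with NumPy 2.4.6 and Numba 0.67.0. All coordinates are from this match and from the annotation of TAIR10.1, not from the build that the submitters name. Gene symbols came from the same annotation and the gene table supplied with it. The main measure used reads of 20 to 24 nt, as RPM, scaled to the genome-matching reads of that length in each library.

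For EVD, a read counted once at full weight if it matched the element anywhere, LTRs included. The LTRs were found as the longest identical stretch on either side of AT5G17125, and the sites that resemble the LTR with blastn 2.17.0 (E-value limit 1e-10, word size 11). A read was assigned to a part of the element by its central base. For annotated loci and windows, a read with several matches was divided equally over them. Loci were counted without regard to strand, so overlapping and antisense genes cannot be told apart. Locus counts are therefore not whole numbers. Their Poisson intervals use the gamma form of the exact interval as an approximation. Their ratio intervals use counts rounded to whole numbers, which can shift an interval where a count is low.

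Counts have exact Poisson 95% intervals, shares exact Clopper-Pearson 95% intervals, and ratios of counts the interval of the conditional binomial, from SciPy 1.17.1. With 1 library per group there was no replicate check, no outlier check and no regrouping of samples, and no test was run. Gene lists were fixed before the data were examined: miRNA sequences, tasiR-ARF, TAS loci, PPR genes with secondary siRNAs, other miRNA targets, the ATCOPIA93 pair and methylation-sensitive genes. A list was described by its median log2 ratio, with a pseudocount of 1 RPM, and by the percentile of that median among 10000 random lists of the same size. Each random list drew, for every member, 1 of the 50 sequences or loci nearest in mean level. The list's own members were not left out, so a random list could draw them. A list of transposable element families had also been fixed. The annotation names no families, so these were not analysed here apart from ATCOPIA93, and annotated pseudogenes took their place.

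Changed pseudogenes and 10 kb windows had at least 100 reads of 24 nt in 1 of the compared libraries and a ratio of at least 4. The loci named in the text were fixed by rule: EVD and ATR, the 4 members of each list with the highest mean level, and, among annotated loci outside the lists with at least 100 reads of 20 to 24 nt in 1 of the compared libraries, the 5 highest and 5 lowest log2 ratios of each generation to WT and of Epi15_F14 to Epi15_F8. miRNAs at least 2-fold apart from WT, and TAS4, were named beyond that rule, after their values were seen. The division of EVD into a gag and a pol part was also made after the data were seen.

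The steps were tested on simulated data. The matcher placed 100% of 2000 simulated reads on their position and strand and matched 0 of those with 1 changed base. These reads came from a random sequence, so reads from repeats were not tried. Windows were drawn at their real levels with counting noise only, and some were changed. For Epi15_F14 against WT over 5839 windows, the 4-fold limit called 0% of windows changed 2-fold, 46% of those changed 4-fold and 98% of those changed 8-fold. It also called 0 unchanged windows, but without variation between libraries this outcome was nearly fixed in advance. Ratio intervals covered the true ratio in at least 96% of simulated pairs.

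Alternatives were fixed before the data were examined: scaling to all reads or to the miRNA list, lengths of 18 to 26 nt, which the files limit to 19 to 26 nt, distinct sequences in place of reads, other treatments of reads with several matches, 1 mismatch, other limits on reads and fold, 50 kb windows, a pseudocount of 10 RPM, and list members with at least 50 reads in every library. Centring on the median feature was added after the data were seen. Figures were drawn with matplotlib 3.10.9.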

Results

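Small RNA was sequenced from flowers of Arabidopsis thaliana Col0 (WT) and of Epi15, an epigenetic recombinant inbred line derived from a cross with the DNA methylation mutant met1, at generations 8, 11 and 14. The design asked how small RNAs of EVADE (EVD), a Ty1/copia long terminal repeat (LTR) retrotransposon of the ATCOPIA93 family, differ between the 3 generations of this line. There were 4 libraries, with 1 library per group and no replicates, so no test between groups was possible and no p-value is given. The libraries held 32688199 reads in WT, 36286730 in Epi15_F8, 30098074 in Epi15_F11 and 31566249 in Epi15_F14. Of the reads of 20 to 24 nt, 20860738 in WT, 22218155 in Epi15_F8, 19490425 in Epi15_F11 and 19383120 in Epi15_F14 matched the genome without mismatch, which is between 91.2% and 91.8% of them. Levels are given as RPM, the read count scaled to these matching reads. The floor for a count of 0 was set at 3 reads, a one-sided 95% limit, or 0.155 RPM in Epi15_F14, the shallowest library, and the two-sided intervals reach somewhat higher. The 95% intervals cover counting error only, since amplified reads are not independent molecules, and they say nothing about variation between plants.

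EVD lies on chromosome 5 from 5629978 to 5635306 in TAIR10.1, is 5329 bp long and includes the annotated pseudogene AT5G17125. EVD-matching reads of 20 to 24 nt were far more abundant in every Epi15 generation than in WT, and were highest in Epi15_F11. WT held 288 such reads, or 13.8 RPM (12.3 to 15.5). The level was 406.1 RPM in Epi15_F8, 29.4-fold above WT (26.2 to 33.2), and 3700.4 RPM in Epi15_F11, 268-fold above WT (239 to 302). In Epi15_F14 it was 2598 RPM, 188-fold above WT (168 to 212). From generation 8 to generation 11 the level was 9.11-fold higher (8.92 to 9.32), and in generation 14 it was 0.702 times that of generation 11 (0.694 to 0.710). When only reads with no match outside EVD were counted, which leaves out all LTR reads, the ratios to WT were 98.9, 1093 and 78.0 in the same order of generations. Reads that matched EVD or ATR, its near-identical second copy, and nowhere else stood at 8.63 RPM in WT, 390.9 in Epi15_F8, 3663 in Epi15_F11 and 860.2 in Epi15_F14.

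**Figure D1:**
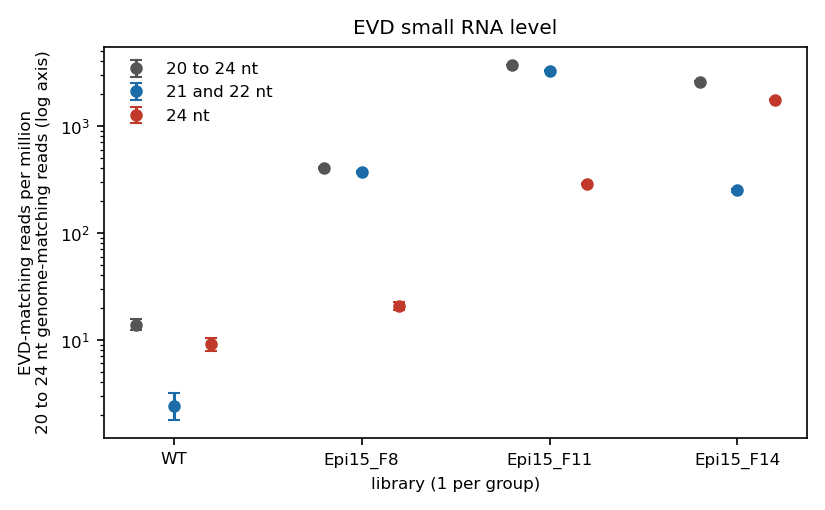
EVD-matching reads in RPM on a log axis, for 1 library per group. Points are all sizes, 21 and 22 nt together, and 24 nt, with exact Poisson 95% intervals; 21 and 22 nt reads are at 3282 RPM in Epi15_F11 and 250.3 RPM in Epi15_F14, while 24 nt reads are at 284.8 and 1759.7 RPM.

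The size of the EVD reads differed between generations. In plants, 21 nt and 22 nt small interfering RNAs (siRNAs) are made by DCL4 and DCL2 and are linked to post-transcriptional silencing, and 24 nt siRNAs are made by DCL3 and are linked to RNA-directed DNA methylation. The 21 nt class made up 71.8% of EVD reads in Epi15_F8 (70.9 to 72.7) and between 71.6% and 72.3% in Epi15_F11, but 4.92% in Epi15_F14 (4.73 to 5.11). The 22 nt class made up 19.4% in Epi15_F8, 16.7% in Epi15_F11 and 4.72% in Epi15_F14. The share of 24 nt reads was 5.09% in Epi15_F8 (4.64 to 5.56), 7.70% in Epi15_F11 (7.50 to 7.89) and 67.7% in Epi15_F14 (67.3 to 68.1). In WT it was 66.0% (60.2 to 71.4), which overlaps the interval of Epi15_F14, at a level of 9.11 RPM against 1759.7 RPM. Reads of 21 and 22 nt together were 8.86-fold higher in Epi15_F11 than in Epi15_F8 (8.66 to 9.07) and 13.1-fold lower in Epi15_F14 than in Epi15_F11 (12.7 to 13.5). Reads of 24 nt were 13.8-fold higher in Epi15_F11 than in Epi15_F8 (12.5 to 15.2) and 6.18-fold higher in Epi15_F14 than in Epi15_F11 (6.01 to 6.36).

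The reads also lay in different parts of the element. Its identical LTRs, each 406 bp long, span 5629978 to 5630383 and 5634901 to 5635306. No gag is annotated, so the open reading frame of 1404 codons was split at the protease motif into a gag part (5630538 to 5631530) and a pol part (5631531 to 5634752), a split made after the data were seen. LTR reads were 0.931% of EVD reads in Epi15_F8 and 0.460% in Epi15_F11 (0.412 to 0.512), against 82.1% in Epi15_F14 (81.8 to 82.5). In WT the share was 11.1% (7.73 to 15.3), from 32 reads. The gag part held 73.7% of the 21 and 22 nt reads in Epi15_F8 and 84.1% in Epi15_F11. The planned 250 bp bins placed the peak at 5631228 to 5631477, with 41.6% of these reads in Epi15_F8 and 47.0% in Epi15_F11. Both strands were present there, with 54.4% antisense reads in the gag part in Epi15_F8 (53.1 to 55.6) and 50.3% in Epi15_F11 (49.9 to 50.7). In Epi15_F14, 21 and 22 nt reads of the gag part fell to 12.6 RPM, 219-fold below Epi15_F11 (193 to 250).

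In the LTRs, 24 nt reads stood at 1.05 RPM in WT (0.661 to 1.60) and 0.945 RPM in Epi15_F8 (0.585 to 1.44), a difference not detectable at this depth. They stood at 8.41 RPM in Epi15_F11 (7.18 to 9.81) and at 1426 RPM in Epi15_F14 (1409 to 1443), 169-fold above Epi15_F11 (145 to 199). Antisense reads were between 63.5% and 64.6% of the 24 nt LTR reads in Epi15_F14 and 91.6% of those of the leader between the 5′ LTR and the gag part (90.4 to 92.7). The most abundant EVD sequence in both Epi15_F8 and Epi15_F11 was AAGACTCAAGAGCTCATCTCT, a sense 21 nt read of the gag part at 5631334 to 5631354 with 1 match in the genome. It was read 461 times in Epi15_F8, 4337 times in Epi15_F11, 3 times in Epi15_F14 and 1 time in WT. In Epi15_F14 the most abundant was ATGTTCGGCCCACTCTCTTGTAGT, an antisense 24 nt read of the LTR placed at 5630022 to 5630045, with 3312 reads. It had 5 matches in the genome and was read 0 times in WT, 1 time in Epi15_F8 and 5 times in Epi15_F11.

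**Figure D2:**
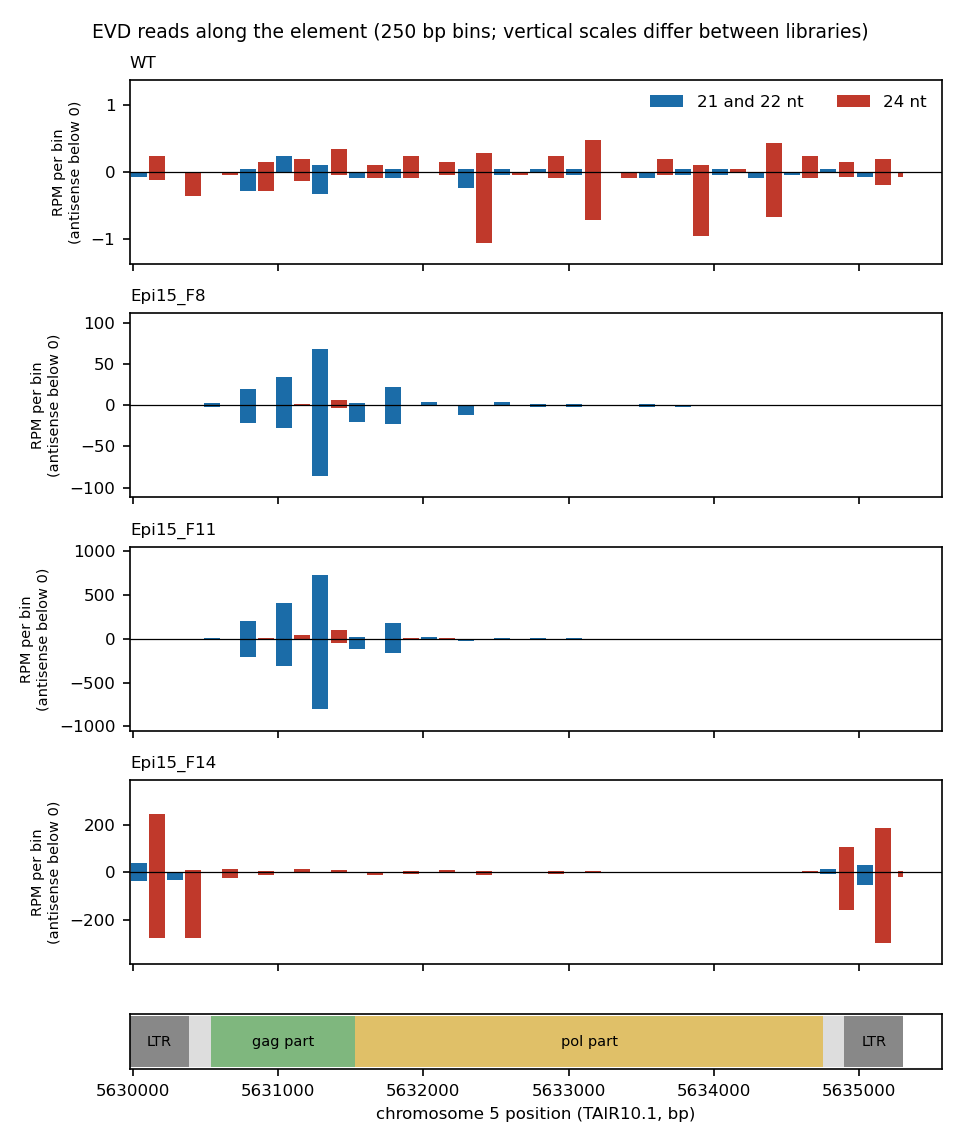
EVD reads in RPM in 250 bp bins along chromosome 5 (TAIR10.1), sense above and antisense below 0, for 21 and 22 nt and for 24 nt reads, with LTR reads divided over both LTRs and a map of the parts underneath. The vertical scale differs between libraries; 21 and 22 nt reads of the gag part lead in Epi15_F8 and Epi15_F11, and 24 nt reads of the LTRs lead in Epi15_F14.

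Most EVD reads could not be separated from ATR, the near-identical second ATCOPIA93 copy (annotated pseudogene AT1G34967, element at chromosome 1 from 12755060 to 12760389). The annotated loci differ at 22 of 4227 bases, and the LTRs are 100% identical. Reads that matched ATR alone numbered 26 in Epi15_F8, 116 in Epi15_F11 and 33 in Epi15_F14, against 1686, 16340 and 1160 reads that matched EVD alone. In WT these were 12 and 16 reads. Since the copies share their LTR sequence, the LTR reads of Epi15_F14 cannot be assigned to 1 copy. In that library, 67.0% of EVD reads also matched a site outside both copies, against 41.7% in WT, 4.03% in Epi15_F8 and 1.18% in Epi15_F11.

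Sites elsewhere in the genome that resemble the EVD LTR also carried 24 nt reads in Epi15_F14. On chromosome 3, the site at 10181983 to 10182388, which overlaps AT3G05255 (an annotated RNA) and AT3G27495 (an uncharacterized protein) and is 98.5% identical to the LTR, had 1072 RPM in Epi15_F14 against 0.815 RPM in WT. A second site on chromosome 3, at 8674785 to 8675191, is 95.4% identical, overlaps AT3G24000, a tetratricopeptide repeat protein gene, and had 299.8 RPM against 0.336 RPM. On chromosome 4, the site at 9496129 to 9496512 within AT4G16880, a leucine-rich repeat protein gene, is 91.5% identical and had 89.9 RPM against 0.144 RPM. At these chromosome 3 sites, most of the reads also match EVD. Inside the AT4G16880 site, however, 378 reads of Epi15_F14 were 1 mismatch from EVD and 595 differed from it at 2 or more bases. At AT4G16880, 810 reads of Epi15_F14 matched no other place, against 0 in WT, 0 in Epi15_F8 and 2 in Epi15_F11.

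**Figure D3:**
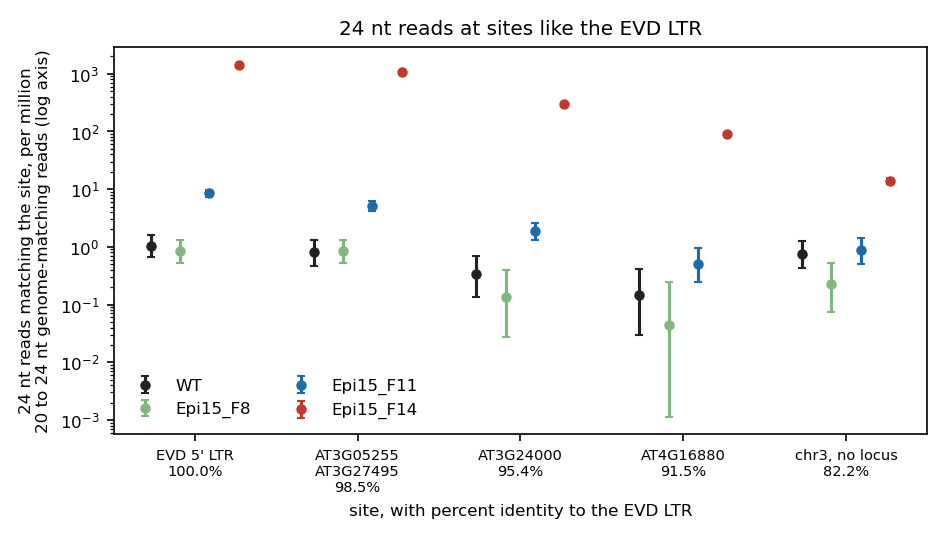
24 nt reads matching the EVD 5′ LTR and 4 sites that resemble it, in RPM on a log axis, with exact Poisson 95% intervals for 1 library per group; sites are ordered by percent identity to the LTR. A read that matches several sites is counted at each, so that sites more like the LTR share more of its reads, and Epi15_F14 ranges from 1424 RPM at the EVD LTR to 13.9 RPM at the site of 82.2% identity.

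The whole libraries differed much less than EVD did. Reads of 24 nt made up 34.0% of genome-matching 20 to 24 nt reads in WT, 34.9% in Epi15_F8, 38.9% in Epi15_F11 and 36.4% in Epi15_F14, with the exact interval in WT at 34.00 to 34.04%. Reads of 21 nt made up 27.7% in WT and between 25.6% and 26.1% in the Epi15 generations, and reads of 22 nt made up 12.9%, 13.6%, 12.3% and 13.0% in the order WT and generations 8, 11 and 14. The single sequence miR166a took 7.27% of all reads in WT, 5.87% in Epi15_F8, 6.72% in Epi15_F11 and 5.91% in Epi15_F14.

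MicroRNAs (miRNAs) and secondary siRNAs served as reference classes outside EVD. Of 38 listed miRNA sequences, 37 had reads. Their median log2 ratio to WT was -0.12 in Epi15_F8, which turns to 0.09 when levels are scaled to the miRNA list itself, 0.03 in Epi15_F11 and 0.04 in Epi15_F14. Among 10000 random lists of sequences matched on mean level, these medians fell at percentiles 0.010, 97.2 and 76.9. The miRNA scaling, here and below, rests mostly on the single sequence miR166a. It gave 2377151 of the 3280392 list reads in WT, 2129432 of 2931273 in Epi15_F8 and 1866158 of 2575410 in Epi15_F14. The 4 most abundant members were miR166a, miR165a, miR158a and miR159a, with ratios to WT in Epi15_F14 of 0.845, 0.744, 0.957 and 0.894. In Epi15_F8, 3 of the 29 members with at least 100 reads were at least 2-fold above WT and 2 were at least 2-fold below. The first were miR397a at 37.6-fold (12.5 to 185), miR408 at 7.10-fold (6.42 to 7.87) and miR845b at 2.12-fold (1.61 to 2.80), of which miR397a and miR408 target copper proteins. The second were miR396a at 0.441 (0.425 to 0.458) and miR399b at 0.498 (0.434 to 0.571).

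The median log2 ratio of the 6 TAS loci, which make trans-acting siRNAs (tasiRNAs), was -0.21 in Epi15_F8, -0.10 in Epi15_F11 and -0.15 in Epi15_F14, at percentiles 0.735, 3.24 and 0.980 of random lists, and each of these turns positive when scaled to the miRNA list. TAS1c, TAS2, TAS3 and TAS1b were the most abundant, with ratios to WT in Epi15_F14 of 0.934, 0.881, 0.897 and 0.870. TAS4, the least abundant, stood apart at 0.228 times WT in Epi15_F8 (0.0571 to 0.728), 0.454 in Epi15_F11 (0.155 to 1.12) and 2.61 in Epi15_F14 (1.47 to 5.15), over 16.5 reads in WT. The tasiR-ARF sequence had log2 ratios of -0.24, -0.32 and -0.40 in the 3 generations, the first of which becomes 0.003 with the miRNA scaling. The 8 pentatricopeptide repeat (PPR) genes with secondary siRNAs had medians of -0.14, 0.20 and -0.13 (percentiles 6.46, 13.2 and 0.540), and the negative ones turn to 0.11 with the miRNA scaling. The most abundant, AT1G63150, AT1G62910, AT1G63080 and AT1G63130, had ratios of 0.904, 0.929, 0.888 and 0.918 in Epi15_F14, and the PPR genes share reads with each other.

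Other miRNA targets with secondary siRNAs, AGO1, AFB3, AFB2 and TIR1, had a median log2 ratio of 0.04 in Epi15_F8, which is -0.02 when scaled to all reads, 0.55 in Epi15_F11 and 0.53 in Epi15_F14 (percentiles 44.7, 80.8 and 92.5). AGO1, which carries miRNAs, stood at 0.971, 1.32 and 1.39 times WT, and AFB3, an auxin receptor gene, at 1.10, 2.45 and 1.64 times. The methylation-sensitive genes had medians of -0.24, 0.20 and 0.09 (percentiles 8.86, 38.9 and 28.9), with 2 members on each side of 0 in Epi15_F11 and Epi15_F14, although all 4 lie above 0 in Epi15_F14 with the miRNA scaling. In Epi15_F14, ROS1 stood at 0.995, SDC at 1.16, FWA at 0.850 and IBM1 at 1.79 times WT. The ATCOPIA93 pair, with shared reads divided between copies over the annotated loci without the LTRs, had medians of 4.93, 8.12 and 4.05, at percentiles 99.97, 99.98 and 99.995. Random lists could draw the pair itself.

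To ask where 24 nt siRNAs changed across the genome, annotated pseudogenes, the class in which EVD and ATR are listed, and 10 kb windows were compared. Those counted had at least 100 reads of 24 nt in 1 of the compared libraries and were at least 4-fold apart. EVD, ATR and the sites like the EVD LTR were not left out, so the higher counts include some of them. The chromosome 1 window from 12750001 to 12760000, which holds part of ATR, had 11.4 RPM in Epi15_F8 and 450.7 RPM in Epi15_F14. The chromosome 3 window from 10180001 to 10190000, which holds AT3G05255 and AT3G27495, had 4.58 and 211.4 RPM. More features were lower than higher in each generation against WT. Among pseudogenes, 85 were lower and 11 higher of 2043 in Epi15_F8, 71 and 26 of 2227 in Epi15_F11, and 75 and 17 of 2074 in Epi15_F14. Between Epi15_F14 and Epi15_F8, 7 of 2016 were higher and 0 lower. Among windows, 124 were lower and 25 higher of 5971 in Epi15_F8, 88 and 47 of 6037 in Epi15_F11, and 104 and 43 of 5980 in Epi15_F14, with 20 higher and 3 lower of 5752 between Epi15_F14 and Epi15_F8. The median window itself was shifted by -0.09, 0.30 and 0.11 log2 units against WT, and the median pseudogene by 0.11, 0.59 and 0.38. Relative to these shifts, 86 pseudogenes were lower and 13 higher in Epi15_F11, and 113 windows were lower and 34 higher. With the miRNA scaling, 71 pseudogenes were lower and 29 higher in Epi15_F14. Distinct sequences in place of reads gave 1 higher and 49 lower of 922 pseudogenes in Epi15_F8 and 0 higher of 912 between Epi15_F14 and Epi15_F8. For windows they gave 4 higher and 40 lower of 3809, and 3 and 0 of 3660. Fewer features were compared, because the limit of 100 then applied to distinct sequences, but the share called higher fell as well. With a 2-fold limit, which was not centred on the median shift, the balance turned in some comparisons. These were 233 higher and 98 lower pseudogenes in Epi15_F11, 112 and 105 in Epi15_F14, and 268 higher and 191 lower windows in Epi15_F11. More stayed lower than higher among pseudogenes in Epi15_F8 (58 higher and 130 lower) and windows in Epi15_F8 (95 and 300) and Epi15_F14 (178 and 219).

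Of the 133 windows that were lower than WT in any generation, 82 were lower in all 3. Of the 56 that were higher in any generation, 21 were higher in all 3. Libraries simulated with no change against a shared WT gave 0 such windows, but they hold counting noise only, under which the 4-fold limit called 0 windows even in a single comparison. Independent lists of the observed sizes would share 2.17 lower and 0.181 higher windows between Epi15_F8 and Epi15_F14, against 95 and 22 observed. Neither value allows for variation between libraries, and part or all of this excess may come from the single shared WT library. In the lower windows the median 24 nt level was 14.4 RPM in WT and 0.603 RPM in the pooled Epi15 libraries. In the higher windows it was 0.839 RPM in WT and 25.7 RPM in Epi15. Chromosome 2 held 32 of the lower windows, chromosome 4 held 19, chromosome 1 held 16, chromosome 5 held 12 and chromosome 3 held 3. Among pseudogenes, 67 of 87 were lower and 8 of 30 higher in all 3 generations.

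**Figure D4:**
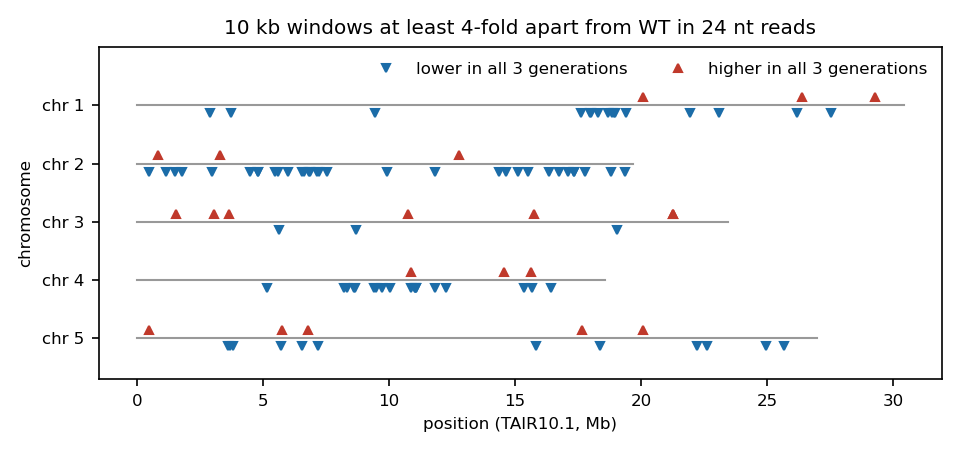
Positions along the 5 chromosomes (TAIR10.1, Mb) of the 10 kb windows at least 4-fold below WT (82) or above WT (21) in 24 nt reads in all 3 generations, with 1 library per group. Chromosome 3 holds 3 lower and 7 higher windows, and chromosome 2 holds 32 lower and 3 higher.

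Outside the lists, the 5 annotated loci with the largest losses of 20 to 24 nt reads were the same in each generation. AT2G04885, a noncoding RNA gene on chromosome 2 (1927015 to 1927479), had 338.8 RPM in WT, 0.675 in Epi15_F8, 1.08 in Epi15_F11 and 0.980 in Epi15_F14. The protein-coding gene AT2G03821 on chromosome 2 (1167303 to 1168206) overlaps AT2G03822 and AT2G03823, and had 1589 reads in WT and 1 in Epi15_F14. The pseudogene AT4G13442 on chromosome 4 (7812745 to 7813967) had 1345 reads in WT and 0 in Epi15_F14. AT1G49440, a pseudogene on chromosome 1 (18302711 to 18304784), had 1194 reads in WT and 0 in Epi15_F11. AT2G16670, a pseudogene on chromosome 2 (7224341 to 7228819), had 47.0 RPM in WT and 0.344 RPM in Epi15_F14. In WT, between 68.7% and 87.5% of the reads of these loci were of 24 nt.

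AT5G42410, AT3G57480 and AT1G70080 were among the 5 highest loci in each generation against WT. AT5G42410, a SAUR-like auxin-responsive gene on chromosome 5 (16964650 to 16965261), had 0.144 RPM in WT and 80.1, 81.7 and 48.6 RPM in generations 8, 11 and 14. AT3G57480, a zinc finger gene on chromosome 3 (21277270 to 21279404), rose from 0.360 RPM to 44.6, 61.1 and 53.5 RPM. AT1G70080, a terpenoid cyclase family gene on chromosome 1 (26394492 to 26397603), rose from 0.144 RPM to 25.8, 44.7 and 48.3 RPM. AT4G32370, a pectin lyase-like gene on chromosome 4 (15625558 to 15627517), had 23.3, 21.7 and 13.9 RPM in the same order, and AT3G08935, a noncoding RNA gene on chromosome 3 (21267424 to 21267750), had 18.2, 29.9 and 26.2 RPM, both from 0.144 RPM in WT. SUP (AT3G23130), the floral zinc finger gene SUPERMAN on chromosome 3 (8242256 to 8243372), had 0.240 RPM in WT, 0 reads in Epi15_F8, 41.8 RPM in Epi15_F11 and 6.04 RPM in Epi15_F14. Of its reads, 94.2% were of 24 nt in Epi15_F11.

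Between generations 8 and 14, AT3G27495, AT4G16880, AT3G24000 and AT3G05255, the loci at sites like the EVD LTR, were the highest together with AT2G11950. The shared reads leave AT3G27495, AT3G24000 and AT3G05255 uncertain. AT2G11950, a pseudogene on chromosome 2 (4819268 to 4825847), had 4.55 RPM in WT, 7.39 in Epi15_F11 and 29.6 in Epi15_F14, and 20 reads in Epi15_F8. The lowest were AT1G14780, a MAC/perforin gene on chromosome 1 (5090809 to 5094152) that overlaps AT1G14790, with 664 reads in Epi15_F8, 291 in Epi15_F11 and 1 in each of Epi15_F14 and WT, and AT1G32140, an F-box gene on chromosome 1 (11562742 to 11564833), with 14.4 RPM in Epi15_F8 and 0.0516 RPM in Epi15_F14. MIR398b (chromosome 5, 4691022 to 4691137), its overlapping gene AT5G14550 and MIR398c were the others, 17.2-fold (15.1 to 19.7), 16.4-fold (14.5 to 18.7) and 17.3-fold (15.2 to 19.8) lower in Epi15_F14 than in Epi15_F8. The mature sequence is shared by MIR398b and MIR398c, so they are uncertain as separate loci.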

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

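The tests of unique reads, library scaling, the WT library and missing sequence for the windows, all tests of the LTR sites, and the tests of scaling, of MIR408 alone and of growth for the miRNAs were chosen after the result was seen.

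The Epi15 generations lay on opposite sides of WT at a few loci, each beyond the counting interval with the main scaling; these differences were not tested, as each group has 1 library. miR408 was 7.10-fold above WT in Epi15_F8 but at 0.675 times WT in Epi15_F11 (0.577 to 0.787) and 0.796 in Epi15_F14 (0.686 to 0.922). MIR398b was at 5.86, 0.280 and 0.341 times WT in generations 8, 11 and 14, MIR398c at 5.86, 0.279 and 0.339 times, and AT5G14550, which overlaps MIR398b, at 5.82, 0.282 and 0.354 times. AFB2 stood at 0.763 in Epi15_F8 (0.593 to 0.993) and 1.51 in Epi15_F11 (1.20 to 1.89). Scaled to the miRNA list, miR408 in Epi15_F14 was at 0.942 (0.812 to 1.09) and AFB2 in Epi15_F8 at 0.910 (0.706 to 1.18), so that both intervals include 1. AT2G11950 stood at 0.198 in Epi15_F8 (0.116 to 0.323), 1.62 in Epi15_F11 (1.24 to 2.12) and 6.50 in Epi15_F14 (5.28 to 8.26).

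EVD reads outside the measured 20 to 24 nt range were also above WT. At 19 nt the ratios to WT were 42.5 (16.3 to 158), 377 (147 to 1386) and 174 (67.6 to 640) in generations 8, 11 and 14, over 4 reads in WT. At 25 to 30 nt they were 17.5 (7.22 to 55.0), 133 (56.7 to 411) and 156 (66.6 to 482), over 5 reads in WT.

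The first pattern is the rise of miRNAs of the copper-linked families miR397, miR398 and miR408 in Epi15_F8, of which MIR397a was also above WT in Epi15_F11, at 5.78-fold (2.19 to 19.2), and stood at 2.58 in Epi15_F14 (0.847 to 9.36). Scaling between libraries is argued against, since the lowest ratio to WT of miR397a, miR408 and MIR398b over 3 scalings was 5.62. Copies of a few molecules are argued against for MIR397a, MIR398b and MIR408 together, with 59 distinct sequences in Epi15_F8 and 28 in WT, a ratio of 2.11, but stay open for MIR408 alone, with 29 and 20, a ratio of 1.45. A response of all copper-linked miRNAs may be the cause, but MIR857 had 1 read in Epi15_F8 and 1 in WT, too few to decide. Growth or harvest of the F8 plants and the generation itself cannot be told apart, because there was 1 library of Epi15_F8.

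The second pattern is the set of 103 windows of 10 kb on the same side of WT in 24 nt reads in all 3 generations. Reads shared between repeats are argued against for 98 of them, 78 lower and 20 higher, which stayed at least 4-fold apart with uniquely matching reads, and scaling is argued against, since the largest shift of the median window was 0.30 log2 units. Of the 79 lower windows with unique reads in WT, 0 lacked them in every generation. This cannot decide on loss of whole windows, because 1 read in 1 generation was enough to pass. A window on chromosome 2 (19370001 to 19380000) passed with 749 unique reads in WT and 2 in each generation. Only 24 of the 82 lower windows held over 5% of the WT level in all 3, and loss of whole windows or of parts stays open. An unlike WT library or WT stock and an inherited state of the line cannot be told apart, because there was 1 WT library. Chromosome segments inherited from met1, which the origin of the line implies, may also account for the pattern and were not tested.

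The third pattern is the 24 nt reads of Epi15_F14 at sites like the EVD LTR. At AT4G16880, EVD or ATR as the only source is argued against by 595 reads (548 to 645) that differ from EVD at 2 or more bases, against 0 in WT. At the site of AT3G05255 and AT3G27495, 17 such reads (9.90 to 27.2) argue the same for a small part, and the rest remain shared with EVD. AT3G24000 had 1 such read (0.0253 to 5.57), so this count does not argue against EVD or ATR as the only source there. Sequencing errors are argued against at AT3G24000 and AT4G16880, where reads with 1 mismatch were 21.5 and 60.1 times those that single errors would give. An altered LTR copy absent from the reference stays open and was not tested.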

How the results depend on the processing

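Centring on the median feature was added after the data were seen, and all other settings were fixed before. No paired analysis was possible because each group has 1 library. A value counts as moved when it leaves its 95% interval, and a count when it changes by over 1.5 times. The causes of the shifts were not tested, except where the setting itself fixes them. Of 275 alternatives, 100 moved and 3 reversed. Among the others, 12 are shares within a library that scaling cannot change, and 2, the TAS medians of Epi15_F11 and Epi15_F14, took the other sign with the miRNA scaling (0.06 and 0.09) inside their intervals.

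The excess of EVD reads over WT held in every generation under each setting tried. In the order Epi15_F8, Epi15_F11 and Epi15_F14, the ratio to WT was 7.86, 18.1 and 14.4 with distinct sequences, whose number the element's length limits. The ratio was 98.9, 1093 and 78.0 with reads specific to EVD, over 16 such reads in WT. It was 35.1 and 223 in Epi15_F8 and Epi15_F14 with the miRNA scaling, and 37.0 and 351 in Epi15_F8 and Epi15_F11 with reads divided by their matches.

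The 24 nt share remained far higher in Epi15_F14 than in the earlier generations. It was 12.4%, 17.1% and 41.4% with distinct sequences and 3.38%, 7.14% and 79.5% with EVD-specific reads. In Epi15_F14 alone it was 66.0% with lengths to 26 nt, 68.5% with divided reads and 66.0% with 1 mismatch. The LTR share was 3.28%, 3.78% and 42.3% with distinct sequences. It was 0%, 0% and 0% with EVD-specific reads, because ATR has the same LTRs. With divided reads it was 0.589%, 0.306% and 78.0%, and with 1 mismatch 81.4% in Epi15_F14.

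The share of 24 nt reads in WT, Epi15_F8, Epi15_F11 and Epi15_F14 was 21.7%, 21.4%, 25.2% and 22.3% of all reads, 26.9%, 27.1%, 31.5% and 28.6% of matching 19 to 26 nt reads, and 47.8%, 47.3%, 48.4% and 47.6% of distinct sequences. Scaled to the miRNA list it is no share and was not given.

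With the miRNA scaling, values against WT that changed sign in Epi15_F8 include the miRNA median, to 0.0866, tasiR-ARF, to 0.00301, the TAS median, to 0.0402, and the PPR median, to 0.11. In Epi15_F14 the miRNA median moved to 0.22 and tasiR-ARF to -0.17, and the TAS median moved to -0.21 when scaled to all reads. Distinct sequences give no value for single sequences.

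Counts of changed pseudogenes fell with distinct sequences to 1 higher and 49 lower of 922 in Epi15_F8 and 3 and 44 of 1039 in Epi15_F11. They were 3 and 44 of 970 in Epi15_F14, and 0 higher of 912 between Epi15_F14 and Epi15_F8. With reads they were 11 higher and 85 lower of 2043, 26 and 71 of 2227, 17 and 75 of 2074, and 7 higher of 2016. The share called higher therefore fell in each comparison, while the share called lower than WT did not fall in any generation. With 30 reads, 133 were lower in Epi15_F8, 40 higher and 107 lower in Epi15_F11, 28 and 117 in Epi15_F14, and 4 lower between Epi15_F14 and Epi15_F8. At 2-fold, 58 were higher and 130 lower in Epi15_F8, 233 higher in Epi15_F11, 112 higher in Epi15_F14, and 52 higher and 3 lower between generations 14 and 8. At 8-fold, 3, 7 and 6 were higher in the generations and 3 between generations 14 and 8. The miRNA scaling gave 29 higher in Epi15_F14, and centring 13 higher in Epi15_F11.

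Counts of changed windows fell with distinct sequences to 4 higher and 40 lower of 3809 in Epi15_F8 and 8 and 32 of 3914 in Epi15_F11. They were 8 and 39 of 3833 in Epi15_F14, and 3 and 0 of 3660 between generations 14 and 8. With reads, 5971, 6037, 5980 and 5752 windows were compared, and the shares called higher and called lower were both larger in each comparison. In 50 kb windows the counts were 4 and 15 of 2152, 7 and 13 of 2150, 6 and 13 of 2154, and 4 and 0 of 2127. At 2-fold they were 95 and 300, 268 and 191, 178 and 219, and 69 and 7. At 8-fold, 16 were higher and 76 lower in Epi15_F8, and 23, 23 and 10 were higher in Epi15_F11, in Epi15_F14 and between generations 14 and 8. Unique reads gave 39 higher in Epi15_F8, and 30 reads gave 6 lower between generations 14 and 8.

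WT held 288 EVD reads and 22 LTR reads of 24 nt, and Epi15_F8 held 21 of the latter, so that LTR folds over either are known within wide intervals.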

Other observations

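The test of registers was chosen after the result was seen.

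The 5′ base of EVD reads differed by size class and generation. Among 24 nt reads, A was the first base in 65.9% in Epi15_F14 (65.4 to 66.4) and 43.0% in Epi15_F11 (41.7 to 44.3), against 59.5% in WT (52.1 to 66.5). Among 21 and 22 nt reads of Epi15_F11, A began 41.3% and U began 35.2%. Small RNAs that begin with A are those that AGO4 and AGO2 usually carry.

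The 500 bp to the right of the 3′ LTR of EVD carried 123 reads of 24 nt in WT, 122 of which matched no other place, and 0 in each Epi15 generation. The 500 bp to the left of the 5′ LTR carried 1 read in WT and 5 in Epi15_F14. Inside the sites like the EVD LTR, 24 nt reads of Epi15_F14 that matched no other place numbered 22 at 98.5% identity, 116 at 95.4%, 808 at 91.5% and 44 at 82.2%. In WT the last site had 15 such reads and the others 0.

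In 24 nt reads, 1 window on chromosome 3 (10770001 to 10780000), named here after its value was seen, rose from 11.6 RPM in WT to 700.6, 901.4 and 775.4 RPM in generations 8, 11 and 14. It holds AT3G28705, AT3G28710 and AT3G28715. A window on chromosome 4 (16420001 to 16430000), also named after its value was seen, fell from 69.5 RPM to 0.360, 0.205 and 0.413 RPM.

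A hypothesis was that 21 nt reads of the EVD gag part arise by phased cutting from 1 start site, as those of TAS loci do. The most used of the 21 nt registers held 15.6% of these reads in Epi15_F11 (15.2 to 15.9), against 4.76% if reads were even over registers. At TAS1a, TAS1b, TAS1c, TAS2 and TAS3, the TAS loci examined, the lowest share was 37.3% (36.3 to 38.3), at TAS3 in WT, and TAS1c reached 80.9%. Phasing as strong as at these loci is argued against, and the excess over an even spread may come from a few abundant sequences or from weaker phasing, which was not tested.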
